A study of Arabidopsis thaliana with 6 samples.

How the data were processed

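Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the transcription factor NLP2 on the Arabidopsis thaliana genome. NLP2 is a member of the NIN-like protein family of nitrate-responsive regulators. Per the labels, an NLP2 mutant line in the Col-0 background carried an NLP2-GFP fusion under the NLP2 promoter, and antibodies against GFP were used for the precipitation. Seedlings, 14 days old by their label, had been starved of nitrogen and were collected either without nitrate (T0) or 30 min after receiving 3 mM nitrate (T30). There were 6 libraries: 2 immunoprecipitated (IP) libraries and 1 input library at each time. The study's design text names 2 biological replicates, but the labels do not say whether the 2 IP libraries of a time came from separate cultures.

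Per the submitters' processing notes, the tools included Bowtie2 2.3.4.1, SAMtools 1.7 and MACS2 2.1.1, with TAIR10 as the genome build. The 4 deposited lists hold peaks, with 1 IP list and 1 input list per time. Each IP list was made by the authors from pooled replicates with a reproducibility filter (IDR), as far as the lists' own names say, so no value per replicate enters any comparison. The authors' fold per peak (a ratio), their −log10 p and −log10 q and their score are the deposited values of each peak; the score equals 10 times −log10 q rounded down in 100% of the IP peaks. The deposited lists also give each peak's summit offset from its start. Read depth is unknown from these lists. The authors' fold is used only to describe, rank or filter peaks within one list, since the lists were called separately.

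Positions are given 1-based on TAIR10. Gene names and neighbours came from a RefSeq gene table of the assembly TAIR10.1, with 27444 protein-coding genes on the 5 nuclear chromosomes; it gave no strand, exons or sequence for use here, and none of its coordinates are printed. Using it assumes that the nuclear chromosomes have the same coordinates in both assemblies. Large offsets were looked for by moving the table in either direction. With the table in place, 42 members of the nitrate and nutrient lists were T30 targets, and under 10 shifts of 5 to 100 kb at most 20 were. Shifts of 500 bp gave 43 and 45 members in the 2 directions, and shifts of 1000 bp gave 41 and 40. The member count therefore cannot tell such small offsets from none. Outside gene-poor regions, 36.7% of summits found at T30 alone lay inside genes with the table in place, against 54.5% and 53.2% with shifts of 1000 bp in the 2 directions. Shifts of 250 bp gave 35.4% and 37.1%, so offsets of that size could not be excluded. All 222 genes of the fixed lists were found in the table by locus code.

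A gene was a target when a summit lay inside it or within 1000 bp of either end. Because strand was missing, this replaced the planned upstream window, "gene end" replaced the transcription start site, and summits were classed as inside a protein-coding gene, within 1000 bp of one or farther away. Motif, k-mer and nitrate-responsive element searches had been planned and were not analysed here, since they need the genome sequence. Peaks were shared when they overlapped by at least 1 bp. A region was gene-poor when fewer than 100 protein-coding genes began within 500 kb on each side of the summit; this class was defined after the data were examined.

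Overlap was tested against 1000 random placements of the T30 peaks, anywhere on the chromosomes, near gene ends or within their own 1 Mb bin (one-sided permutation tests; the last placement was added after the data were examined). Summit locations were compared with the share of bases by two-sided exact binomial tests, with exact Clopper-Pearson 95% intervals that cover counting error only. The 13 gene lists, 11 for nitrate and nutrient functions and 2 for comparison, were fixed before the data were examined. Each was tested against all other protein-coding genes by two-sided Fisher's exact test for T0, T30 and either list, with Benjamini-Hochberg adjustment over 39 tests. Members that were targets at 1 time only were compared with an even split by a two-sided exact binomial test and, as an addition after the data were examined, with the split of all other genes by two-sided Fisher's exact test. These tests take genes or peaks as units and describe the deposited lists; they do not measure the spread between replicates. The threshold was an adjusted p of 0.05.

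Named genes followed a rule set before the data were examined. It took the targets of the 10 peaks with the highest fold in each list and of the 5 highest found at only 1 time. From each gene list it took up to 6 targets by fold and up to 3 other members in alphabetical order, and it added NLP2, NIR1, NIA1, NIA2 and NRT2.1. Some genes that the rule takes are not reported here. On simulated lists, the test of the fixed lists at T30 over 27444 genes recovered 6 planted members in 50 of 50 runs. Without planted members, it called 0 of 1950 tests over T0, T30 and either list. Recovery of fewer members was not simulated. Alternatives included flanks of 500 and 2000 bp, the nearest gene, any base of the peak, stricter folds and the removal of peaks near input peaks. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.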

Results

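Peak lists for NLP2-GFP were compared between nitrogen-starved Arabidopsis seedlings without nitrate (T0) and seedlings given 3 mM nitrate for 30 min (T30). The T0 list held 579 peaks and the T30 list 593, each from 2 pooled IP libraries. The authors' fold per peak ran from 1.87 to 10.5 at T0 (median 2.06) and from 2.01 to 20.9 at T30 (median 2.75). The lowest −log10 q kept was 16.1 at T0 and 20.4 at T30, so the lists do not share a cut-off, and 322 of the T0 peaks lay below the T30 minimum. The input lists held 87 peaks at T0 and 22 at T30. No replicate error can be given for any peak.

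The first comparison asked which genes lay beside NLP2 peaks with and without nitrate. At T30, summits lay in or beside genes of nitrate uptake, nitrate reduction, reductant supply and nitrate-responsive regulation, and at T0 almost none of these genes had one. Of 181 members of the 11 nitrate and nutrient lists, 42 were targets at T30 and 1 at T0. The 1 member found at T0, NLP2 itself, was a target at both times, and the other 41 were targets at T30 alone. Among all other genes that were targets at 1 time only, 57.2% were targets at T30 (Fisher's exact test against these, p = 4.48e-10), and at a q cut-off shared by the lists 84.5% were (Fisher's exact test, p = 0.00210). The 2 times come from separately called lists, so this compares lists and not replicated measurements. Neighbouring genes can also share a peak, which these tests do not allow for.

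The oxidative pentose phosphate pathway and reductant list, which covers the supply of NADPH and reduced ferredoxin, had the largest share of targets at T30 among the 13 lists, with 11 of 24 members against 1.87% of other genes (Fisher's exact test, odds ratio 44.3, adjusted p = 8.80e-12). The transaldolase gene TRA2 (AT5G13420) had a fold of 10.0 and the plastid glucose-6-phosphate transporter gene GPT1 (AT5G54800) a fold of 8.48. Next came the 6-phosphogluconate dehydrogenase gene PGD3 at 7.63, the glucose-6-phosphate dehydrogenase genes G6PD2 at 6.88 and G6PD3 at 6.27, and the root ferredoxin-NADP reductase gene RFNR1 at 6.47. Another 5 members, FD3, PGD1, PGI1, RFNR2 and TKL1, had folds of 3.34 to 5.77; they were named after their values were seen. G6PD1, G6PD4 and G6PD5 were not targets. The 11 targets rested on 11 peaks, and none was a target at T0. This split of 11 to 0 passed the exact binomial test against an even split (adjusted p = 0.0127). Against the split of 481 to 337 among other genes it did not (Fisher's exact test, adjusted p = 0.0503). At a shared q cut-off, other genes split 488 to 84, and even 11 to 0, the outcome furthest towards T30, gives p = 0.380 by Fisher's exact test. That test could therefore not show a surplus at T30.

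Genes of nitrate reduction and its cofactors were targets in 4 of 10 cases at T30 (Fisher's exact test, odds ratio 34.4, adjusted p = 0.000165). UPM1 (AT5G40850), which makes the precursor of the sirohaem cofactor of nitrite reductase, had a fold of 11.6. The nitrite reductase gene NIR1 (AT2G15620) had a summit inside it on chromosome 2 at 6810486, in a peak from 6810316 to 6810771 with a fold of 5.37. The molybdenum cofactor genes CNX6 and CNX2 had folds of 2.42 and 2.32, and CNX1, CNX3 and CNX5 were not targets. The nitrate reductase genes NIA1 and NIA2 had no summit within 1000 bp and so were not counted. Even so, the highest fold of the T30 list, 20.9, belonged to a peak on chromosome 1 from 14165230 to 14165777 whose nearest protein-coding gene was NIA2 (AT1G37130), at more than 2000 bp. NIA1 (AT1G77760) had 4 T30 peaks within 5000 bp, and the highest, on chromosome 1 from 29233968 to 29234646, had a fold of 10.4. With each summit given to its nearest gene, NIA1 and NIA2 joined the list's targets, which then numbered 6.

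Nitrate transport genes were targets in 3 of 23 cases at T30 (Fisher's exact test, odds ratio 7.73, adjusted p = 0.0301). NRT3.1 (AT5G50200), the partner protein of the high-affinity NRT2 transporters, had a summit inside the gene on chromosome 5 at 20436345, with a fold of 12.4. The high-affinity transporter gene NRT2.1 (AT1G08090) had a summit within 1000 bp, on chromosome 1 at 2523943, with a fold of 5.40, and its neighbour NRT2.2 one with a fold of 2.78. CLCa, CLCb and NPF1.1 were not targets, and with the nearest-gene rule the list held 6 targets.

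Among the nitrate-responsive transcription regulators, 7 of 23 were targets at T30 (Fisher's exact test, odds ratio 22.7, adjusted p = 2.20e-06). They included the LOB-domain genes LBD37 with a fold of 7.38 and LBD38 with 5.08, the GARP-family genes HHO3 with 6.92 and HHO2 with 2.83, the bZIP gene TGA4 with 4.90, and the auxin receptor gene AFB3 with 5.27. LBD39, with a fold of 2.79, was named after its value was seen. ANR1, BT1 and BT2 were not targets, although BT1 and BT2 were the genes nearest to T30 peaks with folds of 5.78 and 6.81, within 2000 bp. The nearest-gene rule gave 12 targets for this list.

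Nitrate signalling genes were targets in 5 of 19 cases at T30 (Fisher's exact test, odds ratio 18.5, adjusted p = 0.000165). NLP3, a relative of NLP2, had the highest fold of these at 7.56, followed by NRG2 at 3.66, NLP2 at 2.87, NLP1 at 2.76 and the kinase gene CIPK23 at 2.74. CBL1, CBL9 and CIPK8 were not targets. The list had 3 targets with a 500 bp flank and 3 with the nearest-gene rule, and passed under both. NLP2 (AT4G35270) was the only list member with a peak at both times. Its T0 peak, on chromosome 4 from 16777716 to 16779644, lay inside the gene with a fold of 2.38, and the T30 list held a peak from 16777760 to 16779602 with a fold of 2.04. The seedlings carry an added NLP2 construct, which holds a further copy of NLP2 sequence. The T0 input list also had 2 peaks that overlapped the gene, from 16780191 to 16780701 and from 16781842 to 16782186. Neither overlapped these IP peaks.

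Genes of carbon and ammonium metabolism were also among the T30 targets. Organic acid and carbon skeleton genes were targets in 4 of 26 cases (Fisher's exact test, odds ratio 9.39, adjusted p = 0.00614). They included the 2-oxoglutarate/malate translocator gene DiT1 with a fold of 6.47. The isocitrate dehydrogenase genes IDH1 and IDH6 had folds of 2.87 and 2.78; the IDH1 summit also lay within 1000 bp of NLP2, its neighbour. The isocitrate dehydrogenase gene cICDH was not a target. Ammonium assimilation genes were targets in 3 of 15 cases (Fisher's exact test, odds ratio 12.9, adjusted p = 0.0104), namely ASN2 with a fold of 3.69, the plastid glutamine synthetase gene GLN2 with 3.35 and the ferredoxin-dependent glutamate synthase gene GLU1 with 2.98. ASN1, ASN3 and GDH1 were not targets, and with a 500 bp flank the list kept 2 targets and missed the threshold (Fisher's exact test, adjusted p = 0.0572). It also missed with the nearest-gene rule, at 2 targets (Fisher's exact test, adjusted p = 0.0838).

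Sulfate assimilation genes were targets in 2 of 10 cases, SIR with a fold of 3.67 and APR2 with 2.12 (Fisher's exact test, odds ratio 12.9, adjusted p = 0.0414). With a 2000 bp flank the same count of 2 missed the threshold (Fisher's exact test, adjusted p = 0.0766). It also missed with any base of the peak (2 targets, adjusted p = 0.0516 by Fisher's exact test). Peaks at or above the median fold left 1 target (adjusted p = 0.215 by Fisher's exact test). APR1, APR3 and APS1 were not targets. The remaining nutrient and hormone lists had 1 target each at T30 and did not pass the test: the cytokinin synthesis gene IPT3 (adjusted p = 0.393 by Fisher's exact test), the phosphate-sensing gene SPX4 with a fold of 3.39 and the clock gene LUX with 3.14 (both adjusted p = 0.381 by Fisher's exact test). ABCG14, ARR15, ARR4, NLA, PHO1, PHO2, CCA1, ELF3 and ELF4 were not targets.

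Of the 2 comparison lists, photosynthesis had 0 of 24 targets at T30 and 1 at T0, PSBO1, with a fold of 2.06. GAPA, GAPB and LHCA1 were not targets. The housekeeping list had 1 target of 17 at T30, the glycolytic gene GAPC2 with a fold of 7.75, while ACT2, ACT7 and ACT8 were not targets (Fisher's exact test, adjusted p = 0.455). In all, 8 of the 13 lists passed at T30. At T0, 0 of the 13 passed Fisher's exact test after adjustment, and 0 had an unadjusted p under 0.05. These passes do not show by themselves that a list differed between the times. Against an even split, the oxidative pentose phosphate list passed the exact test of members found at 1 time only. The regulators, with 7 members at T30 alone and 0 at T0 alone, did not after adjustment (p = 0.0156 by the exact binomial test, the smallest that 7 members allow; adjusted p = 0.102). The other 11 lists had 4 such members or fewer, for which the smallest unadjusted p of this exact test is 0.125. They could not pass, so the test says nothing on a difference between the times for them.

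**Figure D1:**
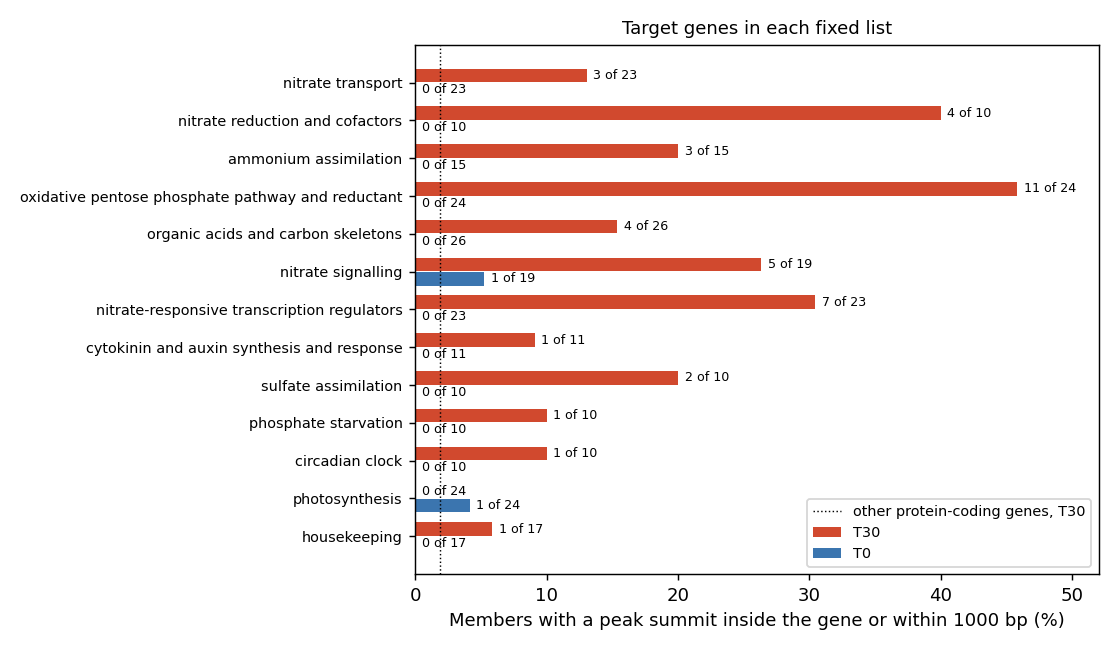
Share of each fixed gene list, in percent on the horizontal axis, with a peak summit inside the gene or within 1000 bp at T30 (red) and T0 (blue), with counts beside the bars and the share of other protein-coding genes at T30 as a dotted line. The oxidative pentose phosphate list reached 11 of 24 at T30 and 0 of 24 at T0.

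Outside the lists, the highest T30 folds included AT2G27520 with a fold of 12.3 and ORG1 (AT5G53450) with 10.7. AT5G13430 shared the TRA2 peak. Of the 10 highest T30 peaks, 4 had no protein-coding gene within 1000 bp: those nearest to NIA2 and NIA1, a peak on chromosome 5 from 12852782 to 12853674 with a fold of 11.6, and a peak at the end of chromosome 2 from 19697672 to 19698285 with a fold of 10.9. The last 2 overlapped input peaks of both times. At T0, the highest fold of 10.5 also belonged to the end of chromosome 2, from 19697673 to 19698284. Only 1 of the 10 highest T0 peaks had protein-coding targets, AT4G20700 and AT4G20703, with a fold of 5.12, and it overlapped a T0 input peak. Most of the 10 highest T0 peaks did so, and all of them were shared with the T30 list. None of the 5 highest peaks found at T0 alone, with folds of 2.43 to 3.33, had a protein-coding gene within 1000 bp.

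The second comparison asked how far the 2 lists coincide. Most NLP2-GFP peaks were found at 1 time only: 114 peaks of each list overlapped a peak of the other, leaving 465 found at T0 alone and 479 at T30 alone. At a q cut-off shared by the lists, 108 T30 peaks were still shared and the peaks found at T0 alone numbered 149. Of the 114 shared peaks, 79 lay in gene-poor regions (69.3%), against 13 of the 479 peaks found at T30 alone (2.71%; Fisher's exact test, odds ratio 80.9, adjusted p = 2.15e-55). Peaks found at T0 alone also lay in such regions more often than those found at T30 alone, in 167 of 465 cases (35.9%; Fisher's exact test, odds ratio 20.1, adjusted p = 6.77e-43). The shared peaks included one on chromosome 5 from 11762588 to 11764034 with a fold of 4.71 at T0, which overlapped a T0 input peak. Random placement of the T30 peaks anywhere gave 4.18 overlaps on average and at most 13, and placement near gene ends gave 2.65 (both permutation p = 0.000999, the smallest that 1000 placements can give). Placement within the same 1 Mb bins gave 5.66 on average (permutation p = 0.000999). Outside gene-poor regions 35 T30 peaks were shared.

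Shared peaks ranked differently within the 2 lists. In the T0 list their median fold was 2.61 against 2.03 for peaks found at T0 alone (permutation p = 1e-05, the smallest the permutations can give). In the T30 list it was 2.48 against 2.91 for peaks found at T30 alone (permutation p = 0.00159). The T0 and T30 lists had 370 and 525 target genes, of which 33 were targets at both times, against 7.08 for independent lists of those sizes (Fisher's exact test, odds ratio 5.29, p = 2.83e-13). Neighbouring genes can share a summit, which this test does not allow for. The shared targets numbered 51 with a 2000 bp flank and 65 with the nearest-gene rule, and a shared q cut-off left 110 T0 targets. Members of the 3 lists with at least 5 targets were not distinguishable in share between targets found at T30 alone and targets at both times (Fisher's exact test, adjusted p of 0.834 to 1), with 33 shared targets to compare. The oxidative pentose phosphate and regulator lists had 0 members among the shared targets, the fewest possible, and still did not pass. For them this test could therefore not show a surplus at T30 alone.

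**Figure D2:**
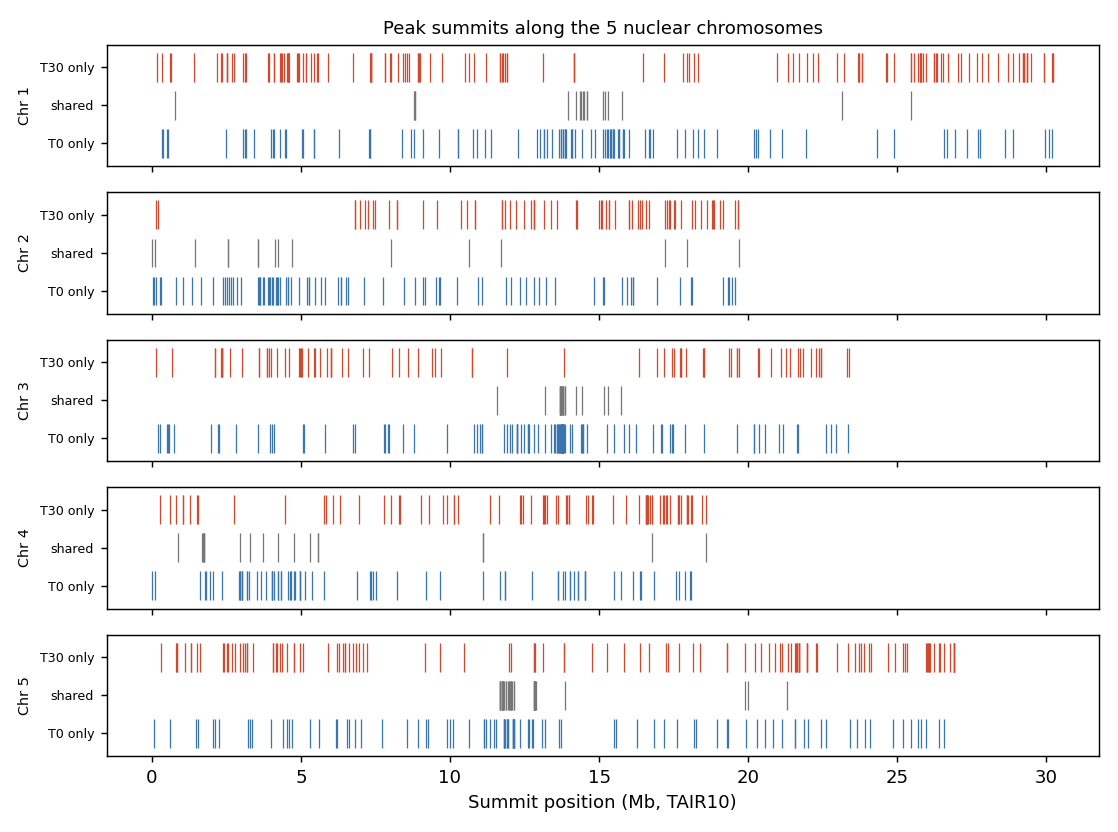
Positions of peak summits on the 5 nuclear chromosomes in Mb (TAIR10), 1 line per summit, for peaks found at T30 alone (red), shared peaks at their T30 summit (grey) and peaks found at T0 alone (blue). Of the 114 shared peaks, 79 lie in gene-poor regions, against 13 of the 479 found at T30 alone.

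The third comparison asked where summits lie relative to genes. At T30, 31.9% of summits lay outside a gene but within 1000 bp of one (95% interval 28.1% to 35.8%, 189 of 593), against 20.4% of bases (exact binomial test, adjusted p = 8.02e-11). At T0 this share was 2.76% (95% interval 1.59% to 4.45%, 16 of 579), below that of bases (exact binomial test, adjusted p = 5.54e-36). Summits inside genes made up 32.9% at T30 and 44.7% at T0, both below the 54.1% of bases inside protein-coding genes (exact binomial tests, adjusted p = 6.21e-25 and 7.27e-06). Gene-poor regions held 42.5% of T0 peaks and 15.5% of T30 peaks, against 12.8% of bases (exact binomial tests, adjusted p = 2.65e-69 and 0.0490).

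Outside gene-poor regions the direction at T0 turned: 75.7% of all T0 summits there lay inside genes, against 60.8% of the bases there. Of the peaks found at T0 alone there, 230 of 298 summits lay inside genes (77.2%), against 171 of 466 for those found at T30 alone (36.7%; Fisher's exact test, odds ratio 5.84, adjusted p = 2.10e-28). The first share was above that of bases there and the second below it (exact binomial tests, adjusted p = 6.65e-09 and 1.11e-24). Peaks found at T0 alone there were also wider, with a median width of 712 bp against 423 bp. Among summits inside genes, 39.6% of those found at T0 alone lay within 500 bp of a gene end, against 82.5% of those found at T30 alone (Fisher's exact test, odds ratio 0.139, p = 2.00e-18). Which end this was could not be told without strand.

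**Figure D3:**
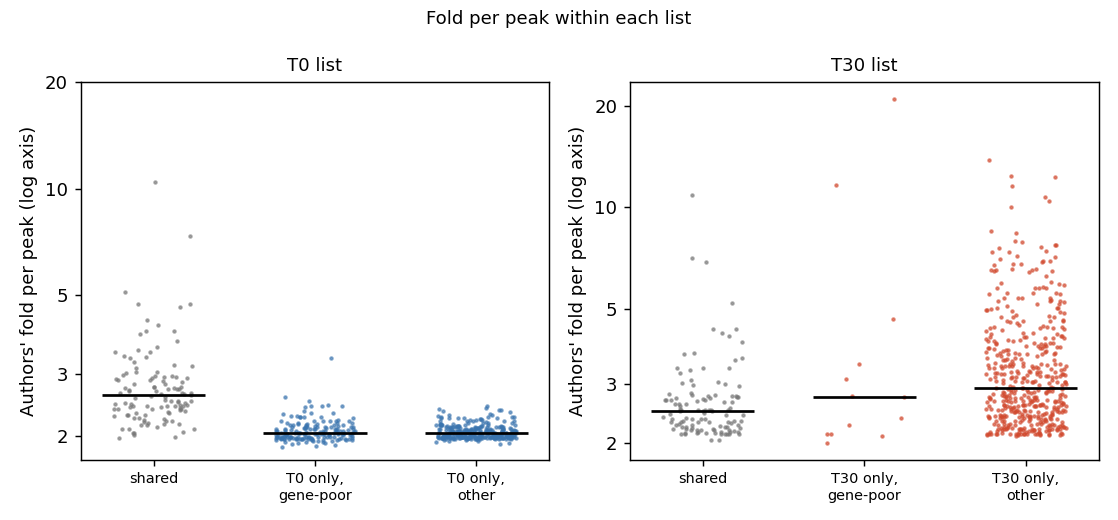
The authors' fold per peak on a log axis for the T0 list (left) and the T30 list (right), 1 point per peak, with black lines at the medians, for shared peaks and for peaks found at 1 time alone in gene-poor regions or elsewhere. Within the T0 list the median was 2.61 for shared peaks, and within the T30 list 2.48; the panels are separate lists and their folds are not to be compared.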

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

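All tests that weigh an explanation in this part were chosen after the data were examined; for those of the q cut-off and of gene ends, the outcomes that would count were set down before these 2 tests were run. The input libraries, which enter no comparison between times, held called peaks of their own: 87 at T0 and 22 at T30, with 14 of each overlapping the other. At T0, 32 IP peaks overlapped a T0 input peak, and at T30, 3 IP peaks overlapped a T30 input peak. The IP lists' names hold the tag noINPUT, whose meaning is not spelled out there. Counted against the T0 input instead, 32 T30 IP peaks overlapped one of its peaks. Genes labelled pseudogene in the gene table were left out of the target counts, and which kinds of sequence carry that label was not examined. Of these, 209 of 3917 (5.34%) had a T0 summit inside or within 1000 bp. The share among other genes was 1.23% (Fisher's exact test, odds ratio 4.53, adjusted p = 1.66e-54 over 24 tests). At T30 the count was 43. Transcribed pseudogenes, annotated as a separate class, had a T0 summit in 14 of 926 cases (1.51%), against 1.66% of other genes (Fisher's exact test, adjusted p = 0.977). Whether the gene-poor location of T0 peaks accounts for the surplus was not tested. The oxidative pentose phosphate list differed between the times by the exact test against an even split, with 11 at T30 alone and 0 at T0 alone (adjusted p = 0.0127), but not against the split of all other genes (Fisher's exact test, adjusted p = 0.0503).

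Shared peaks lay mostly in gene-poor regions. Of them, 24.6% overlapped an input peak, against 0.835% of peaks found at T30 alone (Fisher's exact test, p = 8.63e-18), so regions that stand out without any antibody may account for part of the pattern; of peaks found at T0 alone, 35.9% of which were gene-poor, only 0.860% overlapped one. Regions called as input peaks are not the whole of it: with peaks within 1000 bp of an input peak left out, 62.0% of the remaining shared peaks were gene-poor (49 of 79), against 1.48% at T30 alone (Fisher's exact test, p = 2.03e-41). For binding of NLP2 to nitrate-related genes at both times, the genes nearest to the 79 shared peaks in gene-poor regions were examined. Of these peaks, 0 had a member of the nitrate and nutrient lists as the nearest protein-coding gene. Another count was that 77 lay farther than 1000 bp from any protein-coding gene. Peaks chosen for lying where genes are few would seldom lie beside a list member, so these counts cannot decide on that cause. Input regions raised below the calling threshold, and repeated sequence, which was not analysed here, stay open.

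Peaks found at T0 alone outside gene-poor regions lay inside genes. A lower q cut-off at T0 does not account for this, because among the 83 such peaks at or above the T30 minimum 73.5% still lay inside genes (Fisher's exact test against T30 alone, p = 5.52e-10). Binding placed as at T30 is argued against by the 39.6% of in-gene summits near a gene end, although gene length was not held fixed. Separate sequencing runs of the 2 times stay open: the 2 input lists shared 0 library prefixes, but no label ties a prefix to a run and the IP lists carry none, so whether run and nitrate treatment coincide is not known. A different mode of NLP2 binding without nitrate, the biological alternative in this design, stays open for the same reason. These peaks were also weak within the T0 list, with a median fold of 2.03 and a maximum of 2.43, where the list's minimum was 1.87. No IP from seedlings without the construct was used here to compare them with.

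The NLP2 gene had a peak inside it at both times, with summits 5 bp apart. Input, made without antibody, had 2 peaks at T0 and 0 at T30 that overlapped the gene. NLP2 was 1 of 8 protein-coding genes of 27444 that T0 input peaks overlapped. Extra NLP2 copies from the complementing construct could give such input peaks. However, neither input peak overlapped an IP peak of either time at NLP2. The IP lists' tag noINPUT could mean that some overlapping peaks had been removed. The T30 input had no peak at NLP2, although the seedlings of both times carried the construct. That input list held only 22 called peaks, and the 2 T0 input peaks were weak (folds of 2.01 and 1.80). These counts therefore do not decide on the construct. With peaks within 1000 bp of an input peak left out, the T0 list had no list member among its targets except PSBO1 of the photosynthesis list. Binding of NLP2 beside its own gene after nitrate is a further candidate explanation for the T30 peaks outside the gene: the highest of these within 5000 bp had a fold of 4.95, and the T0 list had none. The construct's promoter may also add copies of such sites, and no library without the construct was used here.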

How the results depend on the processing

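No paired analysis was possible because the deposited lists pool the 2 IP libraries of each time and hold no value per replicate; leaving out a replicate could not be run for the same reason. The planned motif, k-mer and nitrate-responsive element alternatives were not run, for lack of sequence. Removal of gene-poor regions, removal of peaks near input (planned for the peak counts only), a shared q cut-off, length-matched lists, other gene-poor thresholds and the removal of IDH1 were chosen after seeing the data. Of 294 recomputed values, 272 kept their direction, their side of the threshold or, for counts, stayed within 1.5 times. For the fixed lists at T30 this held in 113 of 118 cases, and at T0 in 104 of 104, where no list was called. Read depth is unknown, so its limit on weak peaks cannot be given.

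Keeping peaks at or above the median fold left 298 T0 and 299 T30 peaks, 29 shared peaks (31 when only the T30 list was filtered), 141 T0 targets, 285 T30 targets, 9 shared targets and 1 sulfate target (Fisher's exact test, adjusted p = 0.215). The numbers of peaks and of targets at each time fall by construction. With only the T0 list filtered, 108 shared peaks remained, so the fall in shared peaks came with the T30 filter. Peaks at or above the median −log10 q numbered 295 at T0 and 298 at T30, also by construction. Without gene-poor regions 35 peaks were shared, 298 were found at T0 alone, the T0 share inside genes reversed to 75.7%, above that of bases, and the T0 share farther from genes was 20.4% and missed the threshold. The shared q cut-off gave 110 T0 targets and 149 peaks found at T0 alone. A 2000 bp flank gave 51 shared targets and the nearest-gene rule 65. Ammonium assimilation had 2 targets with a 500 bp flank (Fisher's exact test, adjusted p = 0.0572) and 2 with the nearest gene (adjusted p = 0.0838). Sulfate assimilation had 2 with a 2000 bp flank (Fisher's exact test, adjusted p = 0.0766) and 2 with any base of the peak (adjusted p = 0.0516). Except where construction is named, the cause was not tested.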

Other observations

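All tests in this part were chosen after the data were examined. Targets at T30 that were on the nitrate and nutrient lists had more than 1 peak around them more often than other targets did. Of 42 such targets, 13 had at least 2 T30 summits within 5000 bp of the gene (31.0%), against 48 of 483 other T30 targets (9.94%; Fisher's exact test, odds ratio 4.06, p = 0.000357). Neighbours such as NRT2.1 and NRT2.2, or IDH1 and NLP2, share summits; with targets that share one merged, the counts were 11 of 40 loci against 27 of 315 (Fisher's exact test, p = 0.00123). NIR1 had a peak with a fold of 3.22 beside the one inside it. NIA1, outside this test because its summits lay beyond 1000 bp, had peaks within 5000 bp with folds of 10.4, 5.27, 2.74 and 2.67. It was the nearest protein-coding gene to only 2 T30 summits. More generally, 89 of the 479 summits found at T30 alone had a neighbour within 5000 bp, against 26.4 on average when placed at random in the same 1 Mb bins (permutation p = 0.000999). The value at T0 alone was 52 of 465 against 28.6 (permutation p = 0.00400).

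Genes named as extensins, arabinogalactan proteins or glycine-, proline- or hydroxyproline-rich proteins were T0 targets in 12 of 98 cases (12.2%), against 1.31% of other genes (Fisher's exact test, odds ratio 10.5, adjusted p = 2.43e-07 over 28 tests). They included the extensin genes EXT4 and EXT6, the leucine-rich repeat extensin gene LRX1 and the arabinogalactan protein genes AGP2, AGP3, AGP4 and AGP11. At T30 the count was 5 of 98 (adjusted p = 0.281 by Fisher's exact test). Many such proteins are built from repeats, so repeated coding sequence may contribute to these peaks; this was not analysed here. Among the other 13 name families tried, which included WRKY, MYB, NAC, SAUR and cytochrome P450 genes, none passed after adjustment at either time. Each held only the genes matched by name, so a family may be incomplete. The lowest p among them was 0.0148 by Fisher's exact test, for the genes matched as PP2C at T30 (2 of 10, PP2CA and PP2CG1). MIR827, a microRNA gene tied to phosphate and nitrate supply, was 1 of 4 microRNA genes with a T30 summit inside or within 1000 bp. These were 1.23% of 326 microRNA genes, against 1.78% of other genes (Fisher's exact test, adjusted p = 0.804).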
